A study of Homo sapiens with 6 samples.

How the data were processed

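Gene expression of Hs68 human fibroblasts was measured on 6 microarrays with 2 dyes. Per the labels, each array set RNA of cells treated with an siRNA against FBP1, FBP2 or FBP3 (Cy5) against RNA of cells treated with a control siRNA (Cy3). There were 2 arrays per siRNA, replicate 1 in set A and replicate 2 in set B, and no array with the dyes exchanged. The values used were the log ratios that the authors deposited, 1 per probe and array, taken here as log2. The base is not stated: log10 was excluded because the values reach 9.87 and −9.65, beyond what a 16-bit scanner can give on that scale, and a natural log was not excluded. The scanner, the background correction, the normalization within arrays and the rule for empty values are not given in the sources used here, and scanner intensities were not used here. The deposited columns had medians between −0.10 and −0.01, and 5.42% to 7.22% of the values in set A and 22.6% to 27.6% in set B were empty. The direction of the ratios, knockdown over control, was called likely from the dyes in the labels, with a rule fixed beforehand that each targeted gene had to lie below the array median on both arrays of its own siRNA, as it did.

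Of the 35024 probes, 23995 were listed in the annotation table of the array, 23962 with 1 gene symbol and 33 with several, and 11029 had no gene name here. A gene number in the reference gene table (assembly GRCh38.p14, used for names only) was found for 23942 probes, and 0 symbols changed through it. Probes of the same symbol were averaged, probes without a single symbol were kept apart, and features with a value on all 6 arrays were tested, 17586 in all from 21862 probes, among them 3223 genes with more than 1 probe. Each array was centred on its median over these features. Before that, the medians over the 21862 probes were 0.15 and 0.01 for the siFBP1 arrays of sets A and B, 0.01 and −0.04 for siFBP2, and 0.13 and −0.02 for siFBP3, so all changes are relative to these shifts. No genome coordinates are given, because no build is named for the probes. Y-linked and X-inactivation genes were left out of all gene tables.

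The tests were limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 6 arrays with 1 coefficient per siRNA, so that the siRNAs shared 1 estimate of the spread (3 residual and 4.76 prior degrees of freedom). Each siRNA was tested against 0, each pair of siRNAs against each other, and the mean of the 3 against 0, with Benjamini-Hochberg adjusted p below 0.05. Leaving out an array leaves its siRNA with a lone array that is assumed to vary like the others. Gene counts from such fits include extreme values of that lone array and are not support for single genes. Gene lists were compared with all other features by camera in limma with a preset correlation of 0.01, as the mean log2 shift of the list, with p adjusted over 186 tests of 31 lists in 6 comparisons. This background includes probes without a gene name, whose median lay below that of named genes on every array. The medians were −0.165 and 0.106 on the siFBP1 array of set A, the widest, and −0.02 and 0.01 on the siFBP2 array of set A, the narrowest. Lists of named genes thus start above this background. A count "adjusted over the list alone" uses limma's p-values of the members of that list only. The 33 lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. The lists covered the FBP family and partners, MYC network, MYC-activated and MYC-repressed targets, S phase, G2 and M phase, histones, p53 targets, interferon response, NF-kB and inflammatory mediators, AU-rich mRNAs bound by KHSRP, immediate early genes, collagens and matrix, matrix proteases, contractile genes, TGF-beta and YAP targets, unfolded protein response, heat shock, oxidative stress, cholesterol synthesis, fatty acid metabolism, glycolysis and hypoxia, oxidative phosphorylation, ribosomal proteins, splicing factors, RNA decay, proteasome, apoptosis, and markers of keratinocytes, melanocytes, endothelial, immune, adipocyte and muscle cells. The 2 lists with fewer than 5 measured genes were not tested.

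The named genes were FUBP1, KHSRP, FUBP3, PUF60 and MYC, and in each comparison the 10 genes with the largest positive and the 10 with the largest negative change among those past the threshold and of the same sign in both sets. As no gene passed, these places were filled by the moderated statistic among genes of the same sign in both sets, and they are given as values that did not pass. From each list that passed, 2 to 4 members with the largest absolute change in that comparison are named. Members that passed when adjusted over the list alone are named beside them and were chosen after their values were seen.

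The replicate numbers pair the arrays across siRNAs, because the labels name the same control RNA for the 3 arrays of a set. Within set A, deviations from the siRNA means correlated at −0.12 (siFBP1 with siFBP2), 0.33 (siFBP1 with siFBP3) and −0.01 (siFBP2 with siFBP3). With the replicate block the lists of adipocyte and muscle markers under siFBP2 and of contractile genes between siFBP1 and siFBP3 both moved to adjusted p = 0.051. Alternatives were values without added centring, arrays scaled to one median absolute deviation, quantile normalization, each probe on its own, a robust variance prior, only the arrays compared, the set as a fixed or random block, camera with an estimated correlation, on ranks or replaced by fry, named genes as the only background, and leaving out each array. The spread of the gap between probes with and without values on the other set came from 1000 draws of the probes with replacement, chosen after the data were seen. The fit was tested on simulated data for siFBP1 with 17586 features: of genes changed by 1, 2, 3 and 4 on the log2 scale, 12%, 86%, 96% and 100% were recovered, with 7 false calls. The simulation changed 50 genes at each size. Its noise was independent between arrays, without a shared control RNA or a difference between sets. These shares check the fit and are not its power in the measured data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for tables and plots.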

Results

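Gene expression was measured on 6 microarrays. Each carried RNA from Hs68 cells, a human fibroblast line, treated with 1 of 3 siRNAs and labelled with Cy5. RNA from cells given a control siRNA was labelled with Cy3. The siRNAs were aimed at FBP1, FBP2 and FBP3, the far upstream element binding proteins, which are known for binding a DNA element upstream of the MYC gene. Their present symbols are FUBP1, KHSRP and FUBP3, and KHSRP is also known as a factor in the decay of AU-rich mRNAs. Each siRNA had 2 arrays, 1 in set A and 1 in set B, and the 3 arrays of a set shared the control RNA of that set. Of 35024 probes, 32494 (siFBP1), 32720 (siFBP2) and 33127 (siFBP3) had a value in set A, and 27119, 26449 and 25341 in set B. The 17586 features with a value on all 6 arrays were tested, of which 11324 were named genes and 6262 were probes without a gene name. All changes are log2 ratios of knockdown over control relative to the array median, as mean ± SD of the 2 arrays (n = 2). This direction is called likely. It rests on the dyes in the labels and on each targeted gene lying below the array median on both arrays of its own siRNA. Base 2 was taken for the deposited log ratios, and a natural log, which would make every fold larger, was not excluded by the values. The number of arrays limits the precision. No source says that the sets came from separate cultures, so limma's p-values of single genes measure only the spread between these arrays. A difference between the control RNAs of the 2 sets is part of this spread. The main fit does not take into account that the 3 arrays of a set share 1 control RNA. The camera p-values of the lists instead compare members with other features at a preset correlation of 0.01. They rest largely on the spread across genes and do not measure how a list would vary between repeats.

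KHSRP lay at −1.45 ± 0.71 under siFBP2, 36.7% of the control level. FUBP1 lay at −0.71 ± 0.06 under siFBP1 (61.0% of control) and FUBP3 at −0.50 ± 0.19 under siFBP3 (70.7% of control). KHSRP fell when p was adjusted over the list alone (limma, adjusted p = 0.012 among 15 FBP family and partner genes). Over all features none of the 3 targeted genes passed (adjusted p = 0.290 for KHSRP, 0.518 for FUBP1 and 0.463 for FUBP3). KHSRP was at −1.95 in set A and at −0.94 in set B. The 2 probes of FUBP1 differed under siFBP1, at −1.10 and −1.12 in sets A and B for 1 probe and at −0.41 and −0.23 for the other, and KHSRP had 1 probe. FUBP3 was also at −0.35 ± 0.40 under siFBP1. In set A its 2 probes lay at −0.81 and −0.47 under siFBP1 and at −0.83 and −0.44 under siFBP3. In set B they lay at 0.12 and −0.26 under siFBP1 and at −0.50 and −0.23 under siFBP3. FUBP3 did not differ between siFBP1 and siFBP3 (0.15 ± 0.21, limma, adjusted p = 0.995), so its fall was not particular to siFBP3. FUBP1 under siFBP2 was at 0.63 in set A but −0.48 in set B. GTF2H1, a subunit of the general transcription factor TFIIH, fell under siFBP1 when adjusted over the list alone, at −0.88 ± 0.02 (adjusted p = 0.0495). Another probe of GTF2H1, which lacked a value on the siFBP3 array of set B and was not tested, lay at −0.40 and −0.37 under siFBP1. MYC itself was at 0.07 ± 0.17, −0.32 ± 0.05 and −0.16 ± 0.29 under siFBP1, siFBP2 and siFBP3. The other probe of MYC, which lacked a value on 2 arrays and was not tested, lay at 0.05 under siFBP1 and −1.29 under siFBP2 in set A, and at −0.22 and 0.54 under siFBP3 in sets A and B. PUF60, known as a repressor acting at the same element, was at 0.05 ± 0.31, 0.24 ± 0.26 and −0.04 ± 0.06. None of the 6 means passed limma's test (lowest adjusted p = 0.501, MYC under siFBP2).

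**Figure D1:**
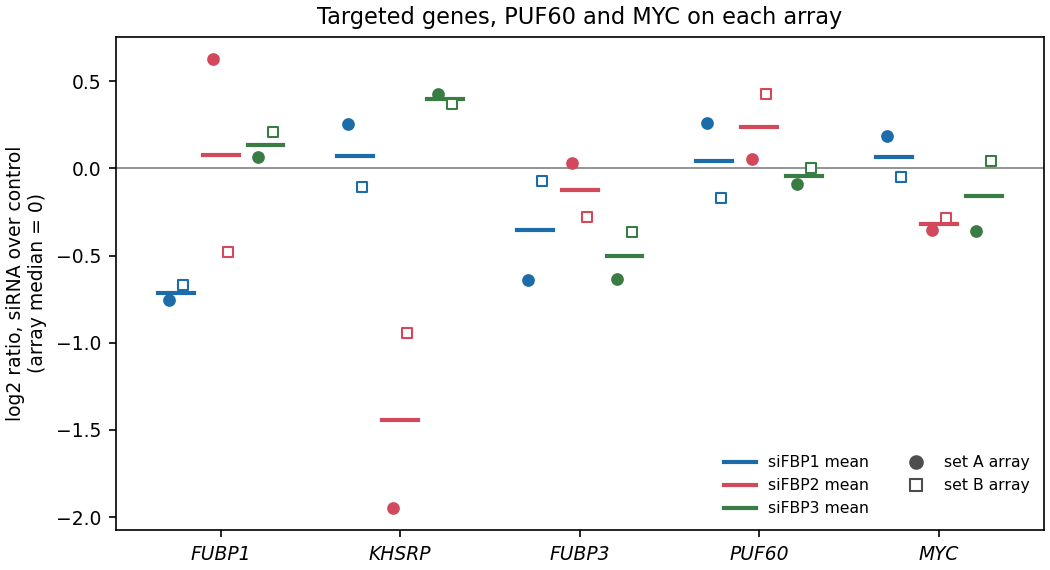
Log2 ratio of siRNA over control (vertical axis, array median at 0) for the 3 targeted genes, PUF60 and MYC, with a filled circle for the set A array, an open square for the set B array and a bar for their mean. KHSRP lies at −1.95 and −0.94 under siFBP2, and FUBP1 and FUBP3 lie below 0 on both arrays of their own siRNA.

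Under siFBP1, the lists of contractile genes and cholesterol synthesis genes were higher than in control cells, in tests that were lost with an estimated correlation (adjusted p = 0.811 for both). With 3 residual degrees of freedom that setting of camera had little power, and 0 lists passed in every comparison. At an unadjusted p under 0.05 it had 1 list under siFBP2, 1 under siFBP3 and 0 in the other comparisons. A loss under it therefore does not tell lists apart. ACTG2, smooth muscle gamma actin, was at 3.38 ± 0.15 (10.4-fold) and CNN1, the actin-binding protein calponin, at 2.23 ± 0.05 (4.70-fold). HMOX1, the heme-degrading enzyme heme oxygenase, was at 2.03 ± 0.25 (4.08-fold). HMGCS1, an early enzyme of the cholesterol pathway, was at 1.38 ± 0.14 and COL5A3, a fibrillar collagen chain, at 1.72 ± 0.33. Further genes that were higher on both arrays were APOC4 (1.37 ± 0.28), the interferon-induced GTPase gene GBP2 (1.35 ± 0.05), LMOD1 (1.34 ± 0.18), KIF3C (1.26 ± 0.32) and the transcription factor gene SOX4 (1.13 ± 0.02). The lower genes named by the rule were CHIC2 (−1.46 ± 0.22), EIF1AX (−1.33 ± 0.31), MTTP (−1.29 ± 0.22), STOML3 (−1.27 ± 0.42) and NEU3 (−1.23 ± 0.23). TSPAN17, LRRC58, STBD1, ZNF41 and MOCS2 followed between −1.22 and −1.03. None of these single genes passed over all features with limma. The count was 0 of 17586, with 1667 at an unadjusted p under 0.05 against 879.3 expected by chance. ACTG2 came closest (adjusted p = 0.051). It passed with a robust variance prior (adjusted p = 0.032) and without added centring (adjusted p = 0.039), where it was the 1 gene counted. The count was 588 when only the 2 siFBP1 arrays were fitted. Without siFBP1 replicate 1, ACTG2 was not counted. The genes counted there were GLI1 (5.39), CTSV (4.50), FEZF2 (−5.63) and PRMT6 (7.01), extreme values of the 1 siFBP1 array left.

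The contractile list rose under siFBP1: its 19 genes stood 0.71 above all other features in the mean (camera, adjusted p = 2.7e-06), a call lost at adjusted p = 0.811 with an estimated correlation. The list medians were smaller, at 0.18 and 0.36 in sets A and B, so a few members carried much of the mean shift. Under siFBP3 the medians were 0.20 and 0.11. Adjusted over the list alone, 7 of the 19 rose and none fell, among them ACTG2, CNN1, ACTA2 (1.84 ± 1.16), the smooth muscle alpha actin gene, and LMOD1, against 0 over all features. The 16 cholesterol synthesis genes rose by 0.61 (adjusted p = 2.6e-07, and adjusted p = 0.811 with an estimated correlation), and 13 of them were higher in both sets. Adjusted over the list alone, 9 of the 16 rose, led by HMGCS1, MVD (1.01 ± 0.40), DHCR7 (0.92 ± 0.49) and IDI1 (0.86 ± 0.32). The 40 collagen and matrix genes rose by 0.35 (adjusted p = 0.00011, and adjusted p = 0.811 with an estimated correlation), with TNC, the matrix protein tenascin, at 1.45 ± 0.43. COL5A3 was the 1 gene past the test adjusted over the list alone. The 32 oxidative phosphorylation genes rose by 0.33 (adjusted p = 2.3e-05, and adjusted p = 0.812 with an estimated correlation), but by 0.17 (adjusted p = 0.024) without siFBP1 replicate 1. No single one of them, such as NDUFS3 (0.74 ± 0.57) or UQCRC2 (0.62 ± 0.58), passed when adjusted over the list alone.

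Other lists that passed under siFBP1 lost their call when 1 of the 2 siFBP1 arrays was left out. The 31 genes of the G2 and M phases fell by 0.50 (−0.50, adjusted p = 4.6e-07, and adjusted p = 0.834 with an estimated correlation), with BIRC5, the apoptosis inhibitor survivin, at −1.18 ± 0.09 and CENPA, a centromere histone, at −1.02 ± 0.91. The shift was −0.98 without siFBP1 replicate 1 and −0.03 (adjusted p = 0.706) without siFBP1 replicate 2, and 0 genes passed when adjusted over the list alone. The 26 interferon response genes rose by 0.40 (adjusted p = 0.00030, and adjusted p = 0.811 with an estimated correlation), and GBP1 (1.47 ± 0.69) and GBP2 rose when adjusted over the list alone. The shift was 0.16 (adjusted p = 0.109) without siFBP1 replicate 1 and 0.65 without siFBP1 replicate 2. TGF-beta and YAP targets (shift 0.36, adjusted p = 0.0033), with the receptor gene TGFBR1 at 1.61 ± 0.67 and LTBP2 at 0.67 ± 0.38, p53 targets (0.33, adjusted p = 0.0096), with CCNG1 at 0.92 ± 0.09 and TP53I3 at 0.73 ± 0.18, and proteasome genes (0.23, adjusted p = 0.0062), with PSME1 at 0.71 ± 0.34 and PSMD12 at −0.79 ± 0.65, rose as lists, with 0 genes past the test adjusted over the list alone. With an estimated correlation these had adjusted p = 0.811, 0.812 and 0.834. Without siFBP1 replicate 1 they were at 0.22 (adjusted p = 0.052), 0.20 (adjusted p = 0.092) and 0.06 (adjusted p = 0.575), and the proteasome was at 0.41 without siFBP1 replicate 2. The 6 histone genes fell (−0.64, adjusted p = 0.033, and adjusted p = 0.811 with an estimated correlation), with H1-4 at −1.51 ± 1.42. When adjusted over the list alone, H2BC21 (−1.12 ± 0.86) and H2AX (−1.06 ± 0.23) fell. The histone call was lost without siFBP1 replicate 1 (−0.41, adjusted p = 0.076), without siFBP1 replicate 2 (−0.87, adjusted p = 0.059) and on ranks (adjusted p = 0.064). Glycolysis and hypoxia genes, with the glucose transporter gene SLC2A3 at 0.88 ± 0.56 and PFKM at 0.69 ± 0.46, rose by 0.21 (adjusted p = 0.043, and adjusted p = 0.811 with an estimated correlation). They did not pass without siFBP1 replicate 1 (0.10, adjusted p = 0.378), after quantile normalization (adjusted p = 0.057), after scaling of the arrays (adjusted p = 0.072) or against named genes alone (adjusted p = 0.189). Without siFBP1 replicate 2 the shift was 0.33, and adjusted over the list alone 0 genes passed. HMOX1 rose when adjusted over the list alone of 22 oxidative stress genes (adjusted p = 0.00066). So did the small heat shock protein genes CRYAB (0.89 ± 0.41), HSPB1 (0.88 ± 0.31) and HSPB8 (0.83 ± 0.11) among 15 heat shock genes, though neither list passed (shift 0.18, adjusted p = 0.282, and shift 0.20, adjusted p = 0.135).

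Under siFBP2, the list of matrix genes was higher and that of the G2 and M phases was lower, in tests that were lost with an estimated correlation (adjusted p = 0.811 and 0.834). MGP, the matrix Gla protein known as an inhibitor of calcification, was at 2.87 ± 0.88 (7.31-fold), the crosslinking enzyme gene TGM2 at 2.30 ± 0.07 (4.94-fold), and CDKN1C, which encodes a cyclin-dependent kinase inhibitor, at 1.70 ± 0.67 (3.25-fold). The kinase gene STYK1 was at −3.28 ± 1.27, and the teneurin gene TENM1 at −2.19 ± 0.04, where the other probe of TENM1, which lacked a value on 1 array and was not tested, lay at 1.12 and 0.72. The plasma membrane calcium pump gene ATP2B4 was at −2.02 ± 0.32 and NT5E, the ectonucleotidase CD73, at −1.76 ± 0.53. Also higher were SNCAIP (1.72 ± 0.41), TNFRSF10D (1.56 ± 0.25), FIBIN (1.54 ± 0.14), the zinc transporter gene SLC39A8 (1.43 ± 0.12), SPANXD, MPC2 and LRRN4CL. Also lower were FLYWCH2 (−2.08 ± 1.05), PLA2G2D (−1.83 ± 0.52), OR51H1, SURF2, DGAT2 (−1.41 ± 0.23) and CAMK4. None passed over all features with limma (0 of 17586, with 2429 at an unadjusted p under 0.05 and 879.3 expected by chance, lowest adjusted p = 0.134). The count was 0 with a robust variance prior and 22 when only the 2 siFBP2 arrays were fitted. Without siFBP2 replicate 1, the genes counted included extreme values of the 1 siFBP2 array left, such as NUTF2 (−9.21) and EBF4 (6.93).

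The 66 ribosomal protein genes rose under siFBP2 by 0.46 against all other features (camera, adjusted p = 2.3e-13, and adjusted p = 0.811 with an estimated correlation). Of these, 57 were higher in both sets, with RPS13 at 0.72 ± 0.48 and RPS15A at 0.71 ± 0.50. When adjusted over the list alone 0 passed. The shift was 0.24 (adjusted p = 0.00033) without siFBP2 replicate 2. The 31 G2 and M phase genes fell by 0.57 (−0.57, adjusted p = 4.9e-07, and adjusted p = 0.834 with an estimated correlation). Of these, 25 were lower in both sets, with BIRC5 at −1.30 ± 0.76, DLGAP5 at −1.19 ± 0.08 and the spindle checkpoint kinase gene BUB1 at −1.18 ± 0.25. Collagen and matrix genes rose by 0.44 (adjusted p = 1.3e-06, and adjusted p = 0.811 with an estimated correlation), with the proteoglycan gene LUM at 1.22 ± 0.68 and COL5A1 at 1.07 ± 0.15. Of the 40, 27 were higher in both sets and 0 were past the test adjusted over the list alone. TGF-beta and YAP targets rose by 0.45 (adjusted p = 0.00017, and adjusted p = 0.811 with an estimated correlation), with PMEPA1 at 0.89 ± 0.19. CCN2, connective tissue growth factor, rose when adjusted over the list alone (1.08 ± 0.08). NF-kB and inflammatory mediators rose by 0.45 (adjusted p = 0.0048, and adjusted p = 0.811 with an estimated correlation), with IL1B at 1.08 ± 0.46, PTGS2, the inducible cyclooxygenase, at 1.07 ± 0.79 and CXCL1 at 1.05 ± 0.78. In the G2 and M phase list and the inflammatory list 0 genes passed when adjusted over the list alone.

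Oxidative phosphorylation genes, with ATP5F1C at 0.78 ± 0.23 and NDUFA1 at 0.78 ± 0.26, rose by 0.39 under siFBP2 (adjusted p = 1.2e-05, and adjusted p = 0.811 with an estimated correlation). They stood at 0.60 without siFBP2 replicate 1 but at 0.17 (adjusted p = 0.089) without siFBP2 replicate 2. Proteasome genes rose by 0.23 (adjusted p = 0.017, and adjusted p = 0.855 with an estimated correlation), with PSME1 at 0.68 ± 0.38 and PSMB7 at −0.93 ± 0.72. They stood at 0.44 without siFBP2 replicate 1 and at 0.01 (adjusted p = 0.855) without siFBP2 replicate 2. Glycolysis and hypoxia genes rose by 0.23 (adjusted p = 0.027, and adjusted p = 0.811 with an estimated correlation), with BNIP3 at 1.02 ± 0.46 and SLC2A3 at 0.89 ± 0.29. They did not pass without siFBP2 replicate 1 (adjusted p = 0.305) or against named genes alone (adjusted p = 0.057). In these 3 lists 0 genes passed when adjusted over the list alone. The 6 adipocyte and muscle markers fell (−0.52, adjusted p = 0.036, and adjusted p = 0.817 with an estimated correlation), with MYH3 at −1.38 ± 1.78. ACTA1 fell when adjusted over the list alone (−0.90 ± 0.30). The list call was lost with the replicate block (adjusted p = 0.051), after scaling (adjusted p = 0.054), after quantile normalization (adjusted p = 0.056) and without siFBP2 replicate 2 (−0.10, adjusted p = 0.671), and the shift was −0.94 without siFBP2 replicate 1. Adjusted over the list alone of 12 MYC-repressed targets, CDKN1C and the kinase inhibitor gene CDKN1B (0.87 ± 0.38) rose while GADD45G (−1.15 ± 0.16) and the cyclin D1 gene CCND1 (−0.95 ± 0.34) fell. The list itself did not pass (shift 0.17, adjusted p = 0.527). DHCR7 rose within the cholesterol list (1.16 ± 0.14), which did not pass as a whole (shift 0.14, adjusted p = 0.318).

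Under siFBP3, the list of cholesterol synthesis genes was higher, in a test that was lost with an estimated correlation (adjusted p = 0.811). HMGCS1 was at 2.27 ± 0.40 (4.83-fold), the sterol demethylation enzyme gene MSMO1 at 1.70 ± 0.25 (3.26-fold), and IDI1, the isopentenyl diphosphate isomerase gene, at 1.67 ± 0.14 (3.19-fold). DHCR7, which encodes the last reductase of the pathway, was at 1.44 ± 0.13 and MVD at 1.34 ± 0.14. Other genes higher on both arrays were SLC46A3 (1.75 ± 0.40), ACAT2 (1.40 ± 0.12), which encodes the enzyme that makes acetoacetyl-CoA, PUDP and the pseudogene HSD17B7P2 (1.62 ± 0.61), whose other probe lay at −0.55 in set A. SPRYD7 (1.36 ± 0.67) was carried by a different probe in each set, 1 at 1.51 in set A and −0.29 in set B and the other at 0.26 and 3.95. PLAC1 was at −3.11 ± 1.33, PRRG3 at −2.66 ± 1.24, the natriuretic peptide receptor gene NPR3 at −2.29 ± 0.62, TAC4 at −2.04 ± 0.33 and CMTM6 at −1.78 ± 0.24. The peptidase gene TRHDE was at −1.73 ± 0.34 and GLO1, the methylglyoxal-detoxifying glyoxalase, at −1.58 ± 0.09. CPLX2 was at −1.54 ± 0.31, LOXL2, a collagen-crosslinking lysyl oxidase, at −1.46 ± 0.14 and the clock-related nuclear receptor gene NR1D2 at −1.39 ± 0.01. Over all features none passed with limma (0 of 17586, with 2019 at an unadjusted p under 0.05 and 879.3 expected by chance, lowest adjusted p = 0.107 for HMGCS1). The count was 0 with a robust variance prior or when only the 2 siFBP3 arrays were fitted. Without siFBP3 replicate 1, the genes counted included extreme values of the 1 siFBP3 array left, such as ENDOU (7.92) and IKZF4 (−7.69).

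The 16 cholesterol synthesis genes rose under siFBP3 by 0.92 (camera, adjusted p = 5.9e-11, and adjusted p = 0.811 with an estimated correlation). Adjusted over the list alone, 10 of the 16 rose, against 0 over all features. SQLE (1.08 ± 0.00) and SREBF2 (0.81 ± 0.36), which encodes the sterol-responsive transcription factor of the pathway, were among the 10. Fatty acid metabolism genes rose by 0.49 (adjusted p = 0.00015, and adjusted p = 0.811 with an estimated correlation), with the desaturase gene SCD past the test adjusted over the list alone (1.49 ± 0.58). ACLY was at 1.11 ± 1.01 and FASN at 0.95 ± 0.36. Ribosomal protein genes rose by 0.35 (adjusted p = 1.1e-08, and adjusted p = 0.834 with an estimated correlation), with 58 of 66 higher in both sets, RPS19 at 0.73 ± 1.30 and RPS15A at 0.67 ± 0.03. Without siFBP3 replicate 2 they rose by 0.23 (adjusted p = 0.020). Oxidative phosphorylation genes rose by 0.445 (adjusted p = 4.6e-08, and adjusted p = 0.811 with an estimated correlation), with 29 of 32 higher in both sets, NDUFA2 at 0.81 ± 0.04 and NDUFA1 at 0.73 ± 0.02. Proteasome genes rose by 0.41 (adjusted p = 1.3e-06, and adjusted p = 0.811 with an estimated correlation), with 25 of 29 higher in both sets, PSME2 at 0.93 ± 0.04 and PSMA3 at 0.71 ± 0.12. p53 targets rose by 0.38 (adjusted p = 0.0042, and adjusted p = 0.811 with an estimated correlation), with TP53INP1 at 0.97 ± 0.42 and RRM2B at 0.95 ± 0.93. In these 4 lists, 0 genes passed when adjusted over the list alone.

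The G2 and M phase genes fell under siFBP3 by 0.43 (−0.43, adjusted p = 7.3e-05, and adjusted p = 0.834 with an estimated correlation), with NEK2 at −1.04 ± 0.76. The cyclin A gene CCNA2 fell when adjusted over the list alone (−1.84 ± 0.71). The list was at −0.92 without siFBP3 replicate 1 and turned to 0.06 (adjusted p = 0.801) without siFBP3 replicate 2. Unfolded protein and ATF4 response genes fell by 0.20 (−0.20, adjusted p = 0.036, and adjusted p = 0.811 with an estimated correlation), with the lipoprotein receptor gene VLDLR past the test adjusted over the list alone (−1.18 ± 0.16) and DDIT3 at −0.75 ± 0.24. They were at −0.36 without siFBP3 replicate 1 and −0.03 (adjusted p = 0.700) without siFBP3 replicate 2. Of the 6 AU-rich mRNAs bound by KHSRP, PTGS2 was at −0.85 ± 0.74, CXCL8, which encodes interleukin 8, at −0.80 ± 0.15 and PLAU, the urokinase gene, at −0.70 ± 0.08. The list fell (−0.54, adjusted p = 0.030, and adjusted p = 0.811 with an estimated correlation). That call was lost without siFBP3 replicate 1 (−0.37, adjusted p = 0.202), after scaling (adjusted p = 0.057) and after quantile normalization (adjusted p = 0.060). The same list did not pass under siFBP2 (shift 0.10, adjusted p = 0.821), which targets KHSRP itself, or under siFBP1 (−0.24, adjusted p = 0.571). Heat shock genes (0.30, adjusted p = 0.017), contractile genes (0.29, adjusted p = 0.022) and splicing factors (0.17, adjusted p = 0.043) rose, each with adjusted p = 0.811 with an estimated correlation. HSPB8 was at 0.87 ± 0.13 and DNAJA1 at 0.59 ± 0.24, ACTA2 at 1.29 ± 0.30 and ACTN1 at 0.55 ± 0.19, and among splicing factors HNRNPL was at −0.85 ± 1.08 and SNRPD3 at 0.64 ± 0.27. Of these, HSPB8 rose when adjusted over the list alone (adjusted p = 0.0498), and in the AU-rich, contractile and splicing lists 0 genes did. Without siFBP3 replicate 1 the 3 lists had adjusted p = 0.192, 0.371 and 0.488, with shifts of 0.22, 0.19 and 0.10. Against named genes alone the contractile list had adjusted p = 0.055 and the splicing list 0.127. The splicing list had adjusted p = 0.052 after scaling. MMP1, the interstitial collagenase gene, fell when adjusted over the list alone of matrix proteases (−2.14 ± 0.87), as did LOXL2 within the collagen list. Neither list passed (shift −0.28, adjusted p = 0.073, and shift 0.05, adjusted p = 0.627).

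**Figure D2:**
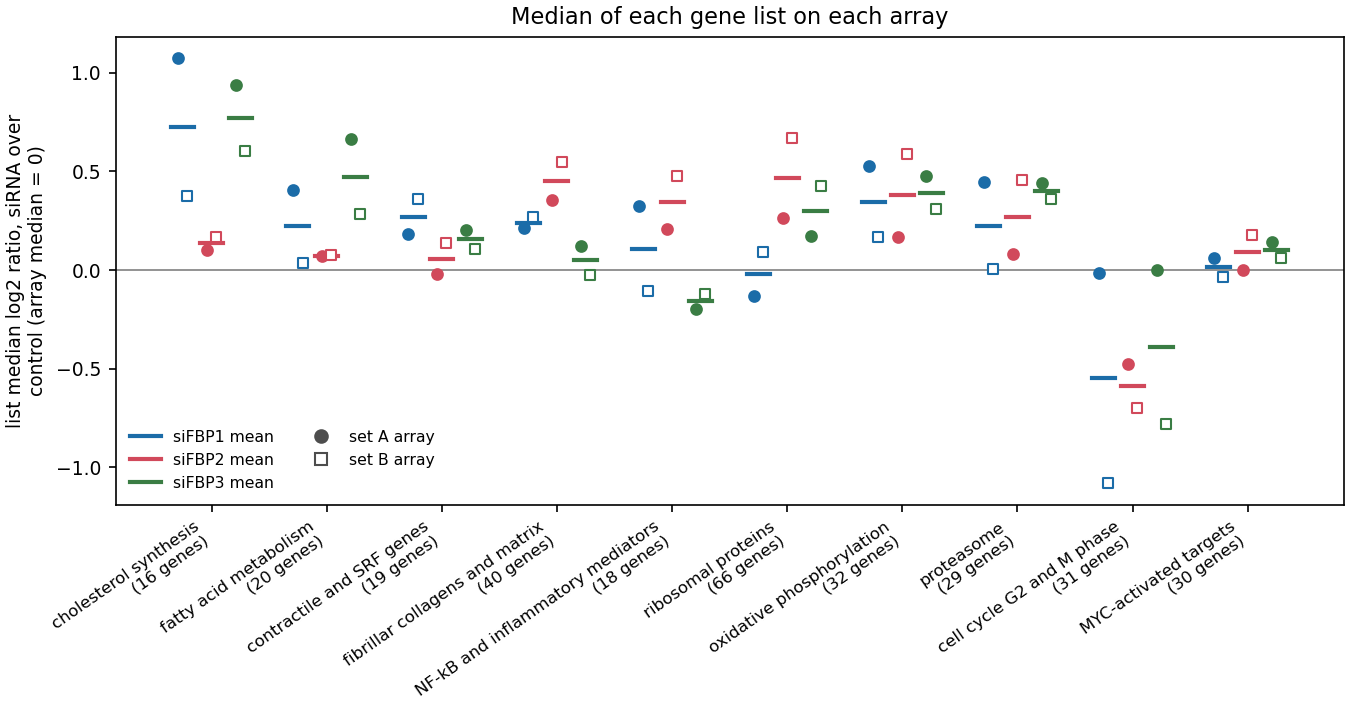
Median log2 ratio of siRNA over control (vertical axis, array median at 0) over the measured genes of 10 lists, with a filled circle for the set A array, an open square for the set B array and a bar for the mean of both. The cholesterol list lies at 1.08 and 0.38 under siFBP1 and at 0.94 and 0.61 under siFBP3 but at 0.10 and 0.17 under siFBP2, and the G2 and M phase list is at −0.02 and −0.00 on the set A arrays of siFBP1 and siFBP3 against −1.08 and −0.78 in set B.

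The differences between siRNAs were tested because the dye effect and, within a set, the control RNA cancel in them. Cholesterol synthesis genes were lower under siFBP2 than under siFBP3 by 0.78 (−0.78, camera, adjusted p = 2.5e-08, and adjusted p = 0.811 with an estimated correlation). The mean of the list was −0.74 in set A and −0.80 in set B. Adjusted over the list alone, 6 of the 16 were lower, led by HMGCS1 (−1.92 ± 0.64), MSMO1 (−1.46 ± 0.31), SQLE (−1.17 ± 0.12) and IDI1 (−1.15 ± 0.07). The same list was higher under siFBP1 than under siFBP2 (0.47, adjusted p = 0.00023, and adjusted p = 0.811 with an estimated correlation), with HMGCS1 at 1.03 ± 0.09 and EBP at 0.96 ± 0.74. The shift was 0.28 (adjusted p = 0.0497) without siFBP1 replicate 1, and 0 genes passed when adjusted over the list alone. It was lower under siFBP1 than under siFBP3 (−0.31, adjusted p = 0.013, and adjusted p = 0.811 with an estimated correlation), with MSMO1 at −0.91 ± 0.29 and HMGCS1 at −0.89 ± 0.55. This call was lost without siFBP1 replicate 2 (−0.12, adjusted p = 0.545) and without siFBP3 replicate 1 (−0.22, adjusted p = 0.262) and stood at −0.50 without siFBP1 replicate 1, with 0 genes past the test adjusted over the list alone. Ribosomal protein genes were lower under siFBP1 than under siFBP2 (−0.46, adjusted p = 2.3e-13, and adjusted p = 0.811 with an estimated correlation), 58 of 66 in both sets, with RPL13A at −0.94 ± 0.15 and RPS13 at −0.75 ± 0.30. The shift was −0.23 (adjusted p = 0.0016) without siFBP2 replicate 2. They were also lower under siFBP1 than under siFBP3 (−0.35, adjusted p = 3.8e-08, and adjusted p = 0.834 with an estimated correlation), 59 of 66 in both sets, with RPS23 at −1.38 ± 0.69 and RPS19 at −0.96 ± 0.49. The shift was −0.23 (adjusted p = 0.0095) without siFBP3 replicate 2. In neither difference did a ribosomal gene pass when adjusted over the list alone (0 genes).

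**Figure D3:**
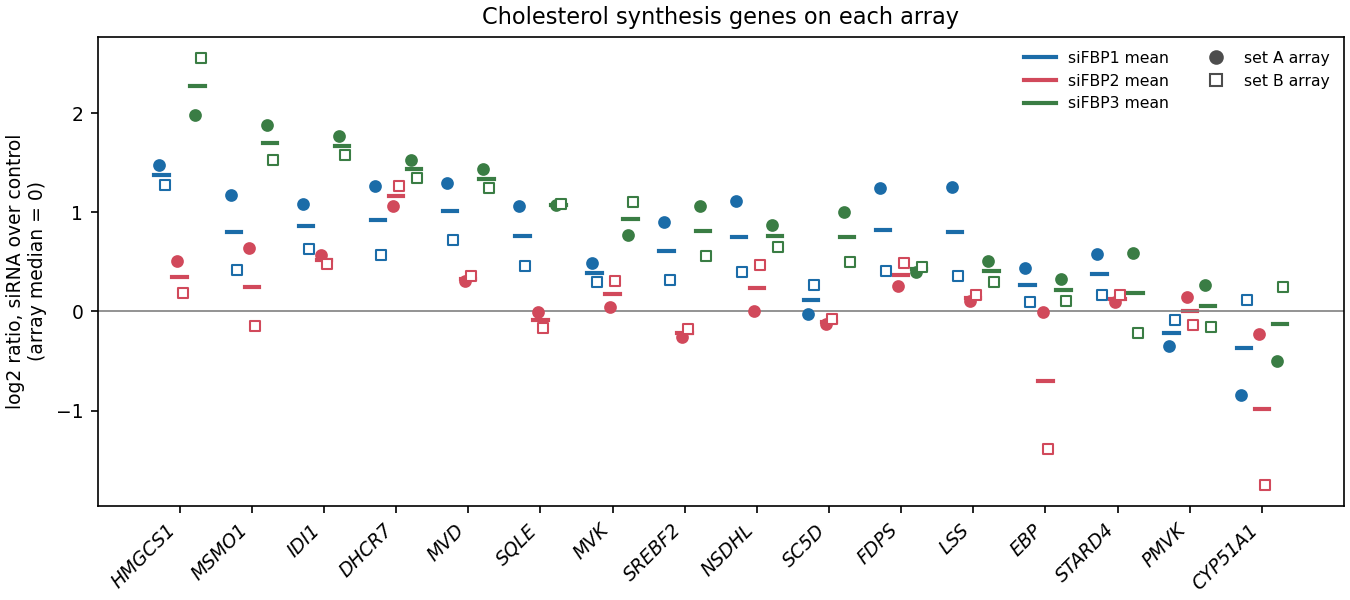
Log2 ratio of siRNA over control (vertical axis, array median at 0) for the 16 measured cholesterol synthesis genes, ordered by their mean under siFBP3, with a filled circle for the set A array, an open square for the set B array and a bar for the mean. HMGCS1 lies at 1.99 and 2.56 under siFBP3, at 1.48 and 1.28 under siFBP1 and at 0.51 and 0.18 under siFBP2.

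Collagen and matrix genes were higher under siFBP2 than under siFBP3 (0.39, adjusted p = 3.7e-05, and adjusted p = 0.811 with an estimated correlation), with LOXL2 past the test adjusted over the list alone (1.61 ± 0.37) and PLOD2 at 1.24 ± 0.48. Inflammatory mediators were higher under siFBP2 than under siFBP3 as well (0.56, adjusted p = 0.00083, and adjusted p = 0.811 with an estimated correlation). PTGS2 (1.92 ± 0.05), IL1B (1.67 ± 0.31) and CXCL8 (1.42 ± 0.02) passed when adjusted over the list alone of 18 genes. Unfolded protein and ATF4 response genes (0.33, adjusted p = 0.0037), with SLC7A11 at −1.62 ± 0.64 and XBP1 at 1.35 ± 0.45, and TGF-beta and YAP targets (0.23, adjusted p = 0.0037), with CCN2 at 1.81 ± 0.42, were higher under siFBP2 than under siFBP3. Fatty acid metabolism genes were lower (−0.34, adjusted p = 0.014), with CPT2 at −1.23 ± 0.08 and SCD at −1.12 ± 0.32. Each of these 3 had adjusted p = 0.811 with an estimated correlation. Without siFBP3 replicate 2 the unfolded protein list was at 0.16 (adjusted p = 0.212) and the TGF-beta list at adjusted p = 0.058. Without siFBP3 replicate 1 the unfolded protein list was at 0.49 and the fatty acid list at −0.19 (adjusted p = 0.275). Without siFBP2 replicates 1 and 2 in turn the fatty acid list was at −0.35 and −0.33, close to its main shift, with adjusted p = 0.056 and 0.051. CCN2 passed when adjusted over the list alone, and 0 genes of the other 2 lists did. The TGF-beta list held INHBA at −3.36 ± 5.91, where 1 array differed from the rest. Single genes named by the rule were TMEM167A (2.49 ± 1.28), ASPN (2.16 ± 0.32), TGM2 (2.07 ± 0.41), PPP1CC, LRRN4CL, CCN3 (1.56 ± 0.18), CDH2 (1.55 ± 0.12) and GNG5 on the siFBP2 side. On the siFBP3 side they were FLYWCH2 (−2.45 ± 1.09), HSD17B7P2, APC (−2.30 ± 0.28), TENM1 (−2.07 ± 0.31), SURF2, ACAT2 (−1.75 ± 0.17), PIR, OR51H1 and HECTD3. The other probe of TENM1, not tested, went the other way in both sets, at 1.12 and 0.72 under siFBP2 and −1.90 and −0.32 under siFBP3. None of the named genes passed with limma over all features (0, with 1079 at an unadjusted p under 0.05 and 879.3 expected by chance, lowest adjusted p = 0.574). The count was 17 and 2 without siFBP2 replicates 1 and 2, 44 and 2 without siFBP3 replicates 1 and 2, and 0 with a robust variance prior.

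Contractile genes were higher under siFBP1 than under siFBP2 (0.59, adjusted p = 0.00030, and adjusted p = 0.811 with an estimated correlation), and ACTG2 (3.37 ± 0.11), CNN1 (2.15 ± 0.04) and LMOD1 (1.46 ± 0.27) passed when adjusted over the list alone. The list did not pass without siFBP1 replicate 2 (0.48, adjusted p = 0.062). HMOX1 (2.21 ± 0.65) and the metallothionein gene MT1F (−1.41 ± 0.17) differed when adjusted over the list alone of oxidative stress genes. The other genes named by the rule were ATP2B4 (2.32 ± 0.62), PPA1 (2.02 ± 0.97), SURF2, TENM1 (1.86 ± 0.19), CLDN1 (1.72 ± 0.46), OR51H1 and the Notch ligand gene JAG1 (1.43 ± 0.10), higher under siFBP1. Those higher under siFBP2 were TMEM167A (−2.34 ± 1.49), SLC39A8 (−1.69 ± 0.15), TGM2 (−1.68 ± 0.55), SRGN, UQCR10 (−1.47 ± 0.11), FGF2 (−1.46 ± 0.23), FIBIN, PLPPR4, TYW3 and IMPA2. The other probe of TENM1, not tested, lay at 0.94 under siFBP1 and 0.72 under siFBP2 in set B. None of the named genes passed with limma over all features (0, with 871 at an unadjusted p under 0.05 and 879.3 expected by chance, lowest adjusted p = 0.648). The count was 2 without siFBP1 replicate 1, 13 and 2 without siFBP2 replicates 1 and 2, and 0 with a robust variance prior.

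Between siFBP1 and siFBP3, collagen and matrix genes were higher under siFBP1 (0.30, adjusted p = 0.0054, and adjusted p = 0.811 with an estimated correlation), with LOXL2 (1.91 ± 0.27) and COL5A3 (1.73 ± 0.30) past the test adjusted over the list alone. The call was lost without siFBP1 replicate 2 (0.29, adjusted p = 0.074) and without siFBP3 replicate 2 (0.18, adjusted p = 0.125). Matrix proteases and inhibitors (0.41, adjusted p = 0.012), with MMP1 at 2.39 ± 0.30 and CTSK, a collagen-degrading cathepsin, at 1.26 ± 0.77, unfolded protein genes (0.24, adjusted p = 0.033), with VLDLR at 1.10 ± 0.26 and SLC7A11 at −0.97 ± 0.72, and TGF-beta targets (0.14, adjusted p = 0.030), with TGFBR1 at 1.69 ± 0.18, TGFBR2 at −1.26 ± 0.06 and INHBA at −3.40 ± 4.94, were higher under siFBP1 in the mean of both sets. The mean of the TGF-beta list was 0.36 in set A but −0.05 in set B, where INHBA was at −6.89. Each of the 3 lists had adjusted p = 0.811 with an estimated correlation. The protease call was lost without siFBP1 replicate 1 (0.23, adjusted p = 0.092), without siFBP3 replicate 2 (0.23, adjusted p = 0.205) and on ranks (adjusted p = 0.064). The unfolded protein call was lost without siFBP1 replicate 1 (adjusted p = 0.104), siFBP1 replicate 2 (adjusted p = 0.054) or siFBP3 replicate 2 (0.08, adjusted p = 0.598) and against named genes alone (adjusted p = 0.061), and stood at 0.41 without siFBP3 replicate 1. The TGF-beta call was lost without siFBP1 replicate 1 (0.00, adjusted p = 0.252), siFBP3 replicate 1 (0.09, adjusted p = 0.124) or siFBP3 replicate 2 (adjusted p = 0.189), on ranks (adjusted p = 0.089) and against named genes alone (adjusted p = 0.057), and stood at 0.27 without siFBP1 replicate 2. Splicing factors were lower under siFBP1 (−0.23, adjusted p = 0.027, and adjusted p = 0.811 with an estimated correlation), with TRA2A at −2.02 ± 1.67 and HNRNPL at −0.90 ± 0.69. This call was lost without siFBP1 replicate 2 (adjusted p = 0.438) or siFBP3 replicate 1 (−0.16, adjusted p = 0.441). In these 4 lists 0 genes passed when adjusted over the list alone.

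Contractile genes were higher under siFBP1 than under siFBP3 (0.41, adjusted p = 0.033, and adjusted p = 0.811 with an estimated correlation), and ACTG2 (3.72 ± 0.90) and CNN1 (1.87 ± 0.65) passed when adjusted over the list alone. The list call was lost with the replicate block (adjusted p = 0.051), against named genes alone (adjusted p = 0.059), on ranks (adjusted p = 0.234) and without siFBP1 replicate 2 (adjusted p = 0.485) or siFBP3 replicate 2 (adjusted p = 0.100). DICER1, the small RNA processing nuclease gene, was at −1.71 ± 0.54 and passed when adjusted over the list alone of RNA decay genes. GTF2H1 was at −1.35 ± 0.30 and passed within the FBP list, and HMOX1 was at 1.66 ± 0.43 and passed within the oxidative stress list. Another probe of GTF2H1, which lacked a value on the siFBP3 array of set B, was not tested. In set A it lay at −0.40 under siFBP1 and −0.255 under siFBP3. Further genes higher under siFBP1 were CMTM6 (2.11 ± 0.06), TRHDE (1.81 ± 0.64), GLO1 (1.80 ± 0.45), RASD1, DENND2D, SLC66A3, the chromatin protein gene HMGA2 (1.68 ± 0.02) and PTPRN. Lower were MIGA1 (−2.48 ± 1.49), SLC46A3 (−2.14 ± 1.22), TMBIM6 (−1.71 ± 0.42), PUDP (−1.66 ± 0.00), UQCR10 (−1.66 ± 0.09), MOCS2, ZHX1 and PLPPR4. None passed with limma over all features (0, with 867 at an unadjusted p under 0.05 and 879.3 expected by chance, lowest adjusted p = 0.318 for ACTG2). The count was 40 and 4 without siFBP3 replicates 1 and 2, and 0 with a robust variance prior.

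Averaged over the 3 siRNAs, IL13RA2, the decoy receptor gene of interleukin 13, was at −1.35 ± 0.33 and NT5E at −1.18 ± 0.21. HMGCS1 (1.33 ± 0.01), DHCR7 (1.17 ± 0.16), IDI1 (1.02 ± 0.17) and MVD (0.89 ± 0.17) were higher together with ACTA2 (1.34 ± 0.55), where each SD is over the 2 sets. ZC2HC1C was at −1.66 ± 0.58, the adhesion receptor gene ADGRE3, whose 2 tested probes differed, at −1.23 ± 0.32, SPINK2 at −1.19 ± 0.26 and SLC25A2 at −1.12 ± 0.20. DEPDC1 was at −1.11 ± 0.44, TRHDE at −0.95 ± 0.08, SOX6, carried by 1 of its 2 tested probes, at −0.91 ± 0.18 and TENM1 at −0.88 ± 0.08. The other probe of TENM1, not tested, lay above 0 under siFBP2 and below 0 under siFBP3. TGM2 (1.05 ± 0.25), ACTG2 (1.02 ± 0.11), TRIB2 (1.02 ± 0.39), SNCAIP (0.94 ± 0.25) and MPC2 (0.78 ± 0.16) completed the higher genes. Some of these means rested mainly on 1 siRNA, whereas ZC2HC1C and IL13RA2 were lower by more than 2-fold with all 3. ACTG2 was at 3.27 and 3.49 under siFBP1 in sets A and B. It was at −0.18 and 0.20 under siFBP2 and at 0.19 and −0.87 under siFBP3. TGM2 was at 2.35 and 2.25 under siFBP2 but at −0.01 and 0.47 under siFBP3. TENM1 was at −2.22 and −2.16 under siFBP2 but at −0.37 and 0.13 under siFBP3. No gene passed with limma (0 of 17586, with 4368 at an unadjusted p under 0.05 and 879.3 expected by chance, lowest adjusted p = 0.052 for HMGCS1). The count was 10 with a robust variance prior, where HMGCS1, IL13RA2, NT5E and DHCR7 passed together with 6 unnamed probes, 7 without added centring and 15 when each probe was tested on its own. It was 54 and 1 without siFBP2 replicates 1 and 2, 87 and 86 without siFBP3 replicates 1 and 2. A dye effect that is the same on all arrays remains in this mean. The main fit also took the 3 arrays of a set, which shared 1 control RNA, as independent. With the set as a random block, 4201 features had an unadjusted p under 0.05. The gap between probes with and without missing values, described below, had the same sign on all 6 arrays (0.27 to 1.21). A trend behind that gap would remain in the mean too.

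The lists that describe MYC did not pass with camera in any comparison. Tested with fry for changes in either direction, the MYC network passed under siFBP2 (adjusted p = 0.028) and MYC-repressed targets under siFBP2 and siFBP3 (adjusted p = 0.019 and 0.045). MYC-activated targets were at shifts of 0.02, 0.04 and 0.05 under siFBP1, siFBP2 and siFBP3 (camera, adjusted p = 0.968, 0.766 and 0.703). ODC1, the first enzyme of polyamine synthesis, was at −0.51 ± 0.18 and APEX1 at 0.43 ± 0.23 under siFBP1. The phosphatase gene CDC25A was at −0.81 ± 0.43 and E2F2 at −0.63 ± 0.00 under siFBP2, and ODC1 was at −0.65 ± 0.13 and CDC25A at −0.63 ± 0.89 under siFBP3. The MYC network list was at 0.16, −0.08 and −0.01 (adjusted p = 0.325, 0.447 and 0.826), and under siFBP2 MLX (0.85 ± 0.40) and RUVBL1 (−0.83 ± 0.02) passed when adjusted over the list alone. MYC-repressed targets were at 0.12, 0.17 and −0.18 (adjusted p = 0.510, 0.527 and 0.259), with GADD45G at −1.11 ± 0.17, which passed when adjusted over the list alone, and DDIT3 at −0.75 ± 0.24 under siFBP3. FBP family and partner genes were at −0.05, 0.02 and 0.14 (adjusted p = 0.666, 0.826 and 0.400), S phase genes at −0.22, −0.17 and −0.11 (adjusted p = 0.060, 0.197 and 0.440). Immediate early genes were at 0.13, 0.22 and −0.11 (adjusted p = 0.400, 0.197 and 0.463), with DUSP6 at 1.34 ± 0.13 under siFBP2, where it passed adjusted over the list alone. RNA decay genes were at 0.03, 0.10 and 0.17 (adjusted p = 0.808, 0.482 and 0.145), apoptosis regulators at 0.16, 0.09 and 0.15 (adjusted p = 0.119, 0.527 and 0.308), and oxidative stress genes under siFBP2 and siFBP3 at 0.09 and 0.21 (adjusted p = 0.520 and 0.052). Markers of cells other than fibroblasts did not pass for keratinocytes (−0.09, −0.07 and −0.43, adjusted p = 0.556, 0.795 and 0.082) or immune cells (−0.10, 0.10 and −0.04, adjusted p = 0.831, 0.707 and 0.853). The 4 measured endothelial and 3 melanocyte markers were too few for the test, and their medians lay between −0.87 and 0.13 and between −0.03 and 0.54 across the 6 arrays.

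Features beyond 2-fold on both arrays of a siRNA were 19 higher and 42 lower for siFBP1, 32 and 81 for siFBP2, and 21 and 101 for siFBP3. Named genes among them were 18 and 24, 25 and 59, and 17 and 60, and 23, 20 and 31 features went beyond 2-fold in opposite directions on the 2 arrays. ZC2HC1C and IL13RA2 were lower by more than 2-fold with all 3 siRNAs. ACTA2 and HMGCS1 were higher with siFBP1 and siFBP3, DHCR7 was higher and NT5E and TRHDE were lower with siFBP2 and siFBP3. ADGRE3 was lower with siFBP1 and siFBP3, and CRISPLD1 and CNTNAP4 were lower with siFBP1 and siFBP2, all chosen after their values were seen. Of the 2 probes of ADGRE3, 1 was beyond 2-fold on both arrays of siFBP1 and of siFBP3. The other lay at −0.47 and −0.24 under siFBP1 and at −1.45 and −0.35 under siFBP3. The lower sets shared 6 features for siFBP1 and siFBP2, 6 for siFBP1 and siFBP3 and 5 for siFBP2 and siFBP3, against 0.193, 0.241 and 0.465 for independent sets and 1, 3 and 8 in simulated arrays that share a control and hold no effect. The higher sets shared 0, 2 and 1, against 0.035, 0.023 and 0.038 for independent sets and 6, 6 and 4 in that simulation. Part of any overlap within a set may come from the shared control RNA. The simulation was not repeated, and it gave knockdown and control the same noise variance with all control noise shared within a set. Its counts depend on that setting and are not a measured background. With arrays scaled to one spread, the 2-fold totals of 61 (siFBP1) and 113 (siFBP2) became 117 and 59.

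Across features, which are not independent replicates, the 2 arrays of a siRNA correlated at a mean r of 0.257 (range 0.237 to 0.279 over 3 pairs). Arrays of different siRNAs correlated at 0.268 within a set (range 0.201 to 0.477) and at 0.193 between sets (range 0.064 to 0.377), where no control RNA was shared. In simulated arrays without any effect the within-set value was 0.507 and the between-set value was 0.00. The simulation gave knockdown and control the same noise variance and shared all control noise within a set. Its within-set value follows from that setting, and the measured 0.268 lay below it. It therefore does not show how much of the measured correlation comes from the control. The covariance was 0.072 for the same siRNA, 0.078 for different siRNAs within a set (0.109 in the simulation) and 0.065 for different siRNAs between sets. Of the 6 ways to pair the arrays of the sets, the real one had the highest mean r, next to 0.249 for another, which gives a one-sided exact permutation p of 0.167, the smallest this design allows. The siFBP2 array of set B correlated at 0.377 with the siFBP1 array of set A and at 0.329 with the siFBP3 array of set A, and at 0.237 with the siFBP2 array of set A. Profiles of the differences between siRNAs correlated between the sets at −0.08 for siFBP1 minus siFBP2, 0.205 for siFBP1 minus siFBP3 and 0.02 for siFBP2 minus siFBP3.

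Probes that lacked values on the arrays of the other set had lower log ratios on every array. On the siFBP1 array of set A, the median log ratio was −0.88 for probes with a value on 0 of the 3 arrays of set B and 0.15 for probes with a value on all 3. This gap was 1.03, 0.42 and 1.21 for siFBP1, siFBP2 and siFBP3 in set A and 0.67, 1.18 and 0.27 in set B. The 3 arrays with the widest gaps correlated with each other more than any other pair (r = 0.477, 0.377 and 0.329). Each same-siRNA pair joined an array with a wide gap to an array with a narrower gap. The correlation between arrays thus cannot be told apart from the gap. The gaps of set B rest on 47, 55 and 63 probes with a value on 0 of the other arrays, against 3451, 3404 and 3919 in set A. With the probes redrawn 1000 times, the gap differed between siFBP1 and siFBP2 by 0.61 ± 0.02 (SE) in set A and −0.51 ± 0.19 in set B, and between siFBP2 and siFBP3 by −0.80 ± 0.02 and 0.91 ± 0.22. Taken instead from the probes with a value on 2 of the other arrays, 836 to 913 in set B, these differences were 0.27 ± 0.02 and −0.35 ± 0.04, and −0.29 ± 0.02 and 0.33 ± 0.06. Across the 6 arrays the medians of 5 lists were compared with the gap, and none passed. The correlation r was 0.807 for oxidative phosphorylation, 0.593 for the proteasome, 0.526 for the G2 and M phases, 0.373 for cholesterol synthesis and −0.077 for ribosomal proteins (exact permutation p = 0.096, 0.239, 0.283, 0.428 and 0.881).

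**Figure D4:**
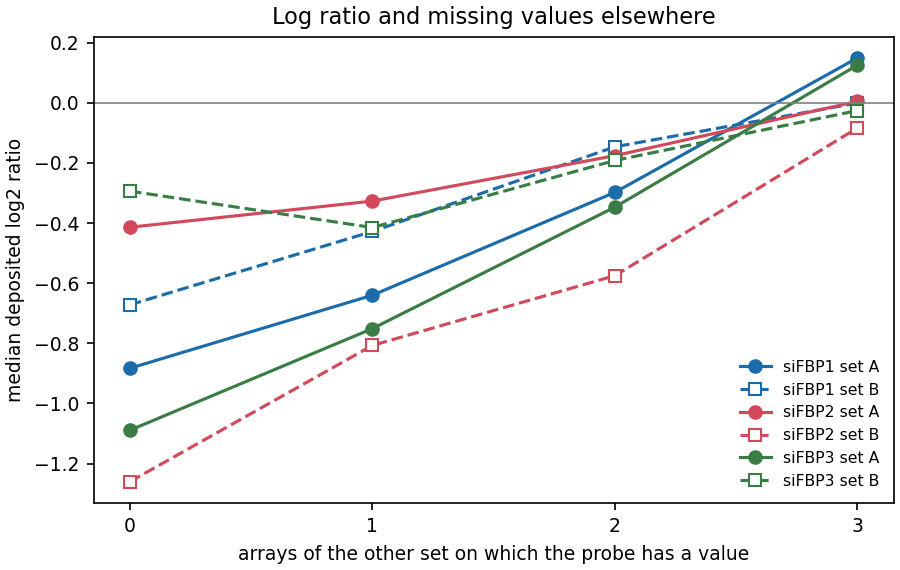
Median deposited log2 ratio (vertical axis) of the probes of each array, by the number of arrays of the other set on which the probe has a value (horizontal axis, 0 to 3), with filled circles and solid lines for set A and open squares and dashed lines for set B. On all 6 arrays the probes with a value on 3 other arrays lie above those with a value on 0.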

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

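All technical tests in this part were chosen after the results they bear on had been seen. The 17 results listed here were singled out because a gene list differed between siRNAs in a test of the difference itself (camera with a preset correlation, adjusted over 186 tests), and each of them was lost with an estimated correlation (adjusted p = 0.811 to 0.834).

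Cholesterol synthesis genes differed by −0.78 between siFBP2 and siFBP3, and were 0.47 higher under siFBP1 than siFBP2 and −0.31 under siFBP1 relative to siFBP3. A trend with spot brightness as the whole cause would have to change sign between the sets, because the gap between probes with and without values on the other set differs between siFBP2 and siFBP3 by −0.80 ± 0.02 (SE over redrawn probes) in set A and 0.91 ± 0.22 in set B, where it rests on 55 and 63 probes. Oxidative phosphorylation genes did change sign (−0.28 and 0.19). Ribosomal protein genes did not, at 0.06 ± 0.03 (SE over genes) and 0.18 ± 0.04, so the gap does not predict the shift of every list. The cholesterol genes were at −0.74 ± 0.13 and −0.80 ± 0.20, which argues against the trend as the whole cause as far as the gap stands for brightness. A part of the set A difference stays open because the gap is not a measured brightness. By design a gene-specific dye effect that is the same on all arrays cancels between siRNAs, which argues against it as the cause of the difference itself (mean of the list −0.77, not a separate test). The target of each siRNA and effects of its sequence on other transcripts both stay open and untested, and a second sequence against the same gene would part them.

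Ribosomal protein genes were at −0.46 under siFBP1 relative to siFBP2 and at −0.35 relative to siFBP3. The gap between probes differs between siFBP1 and siFBP2 by 0.61 ± 0.02 (SE over redrawn probes) in set A and −0.51 ± 0.19 in set B, where it rests on 47 and 55 probes, and oxidative phosphorylation genes changed sign with it (0.29 and −0.38), but ribosomal protein genes were at −0.37 ± 0.03 (SE over genes) and −0.53 ± 0.03. As far as the gap stands for brightness, this argues against the trend as the whole cause of the difference from siFBP2. A part stays open for set B, where both lists moved together. The gap comes from probes with missing values, while the tested ribosomal protein genes had values on all 6 arrays. A trend among probes without missing values is therefore not excluded. For the difference from siFBP3 (−0.30 and −0.35 in sets A and B) the trend cannot be told apart from other causes. The gap there differs by −0.18 ± 0.02 and 0.40 ± 0.17 from probes with a value on 0 of the other arrays. From those with a value on 2 it differs by −0.03 ± 0.02 and −0.02 ± 0.05. Between siFBP1 and siFBP3, oxidative phosphorylation genes were at 0.01 ± 0.06 (SE over genes) and −0.20 ± 0.06. They did not follow the gap from probes with a value on 0. By design a dye effect that is the same on all arrays cancels in these differences (mean of the list −0.45 against siFBP2, not a separate test), and the target of the siRNA and effects of its sequence on other transcripts stay open and untested. For the height of oxidative phosphorylation and proteasome genes above the array median the brightness trend cannot be told apart from an effect of the siRNAs: across the 6 arrays r with the gap was 0.81 and 0.593 (rho 0.66 and 0.60), but −0.077 (rho −0.14) for ribosomal protein genes, none past exact permutation (p = 0.096, 0.239 and 0.881 for r and 0.175, 0.242 and 0.803 for rho, adjusted p = 0.472, 0.472 and 0.881 for r and 0.403, 0.403 and 0.803 for rho over 5 such relations), and r was 0.91, 0.95 and 0.40 without the 2 arrays farthest from the median gap.

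Genes of the G2 and M phases had list medians of −0.17 ± 0.27 (SD) on the 3 arrays of set A and −0.86 ± 0.20 on the 3 of set B (two-sided exact permutation p = 0.10, the smallest possible with 3 arrays against 3). By design a gene-specific dye effect that is the same on all arrays leaves the sets alike, which argues against it as the cause of the set difference itself (−0.70 on average in set B relative to set A, not a separate test). The difference was −0.93 for siFBP1, −0.92 for siFBP3 and −0.24 for siFBP2, so the control RNA of set B may be the cause of part of it and cannot be told apart from a difference between the treated cultures of the sets, because each set has 1 control. Between siFBP1 and siFBP2 the list did not pass (shift 0.06, adjusted p = 0.654, with means of 0.42 in set A and −0.27 in set B), and an effect of the siRNA targets was not tested apart from this.

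Contractile genes differed by 0.59 between siFBP1 and siFBP2 and by 0.41 between siFBP1 and siFBP3. Collagen and matrix genes differed by 0.30 between siFBP1 and siFBP3 and by 0.39 between siFBP2 and siFBP3. TGF-beta and YAP targets differed by 0.14 between siFBP1 and siFBP3 (means of 0.36 in set A and −0.05 in set B) and by 0.23 between siFBP2 and siFBP3. Unfolded protein and ATF4 response genes differed by 0.24 and 0.33 in the same pairs. Matrix proteases and inhibitors differed by 0.41 and splicing factors by −0.23 between siFBP1 and siFBP3. NF-kB and inflammatory mediators differed by 0.56 and fatty acid metabolism genes by −0.34 between siFBP2 and siFBP3.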

How the results depend on the processing

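Array scaling, quantile normalization and named genes as the only background were chosen for the list tests after seeing the data. Of the 49 list calls, 21 held under all settings other than an estimated correlation and fry, under which 0 lists passed in each of the 6 comparisons (main counts 11, 9 and 12 for siFBP1, siFBP2 and siFBP3, and 3, 8 and 6 for siFBP1 minus siFBP2, siFBP1 minus siFBP3 and siFBP2 minus siFBP3). Camera with an estimated correlation had little power with 3 residual degrees of freedom, so its losses do not tell the calls apart. Fry's lowest adjusted p was 0.356, and 27 of its 186 tests for changes in either direction passed, among them MYC-repressed targets under siFBP2 and siFBP3 and the MYC network under siFBP2. Scaling ended 4 calls, quantile normalization 3, ranks 4, named background 7 and the replicate block 2 (adjusted p = 0.051 for both, with no other call changed), and values without added centring 0. Leaving out an array ended 28, and moved the G2 and M phase list under siFBP3 to −0.92 without siFBP3 replicate 1 and, reversed, to 0.057 without siFBP3 replicate 2. List counts over leave-one-out ranged over 7 to 11 (siFBP1), 7 to 9 (siFBP2), 10 to 14 (siFBP3), 3 to 8, 6 to 11 and 6 to 9 (the differences in the same order). Gene counts, 0 in all 7 comparisons, became 1 (siFBP1) and 7 (mean) without added centring, 15 (mean) with each probe on its own, and 1 (siFBP1) and 10 (mean) with a robust prior, and stayed 0 with scaling, quantile normalization and the set as a fixed or random block (consensus correlation 0.017). With only the arrays compared they became 588 (siFBP1) and 22 (siFBP2), where 1 residual degree of freedom was joined to 130 and 15.3 prior ones, against 4.76 with all arrays. Leave-one-out gene counts ranged from 0 to 4 (siFBP1), 70 (siFBP2), 80 (siFBP3), 13, 40 and 44 (the differences in the order above) and 87 (mean). The targeted genes kept their direction and stayed short of the threshold in all settings run. The same-siRNA correlation of 0.257 was 0.209 over all features with both values and 0.313 by Spearman, and the 2-fold totals became 117 (siFBP1) and 59 (siFBP2) with scaling, and 553, 873 and 885 at 1.5-fold; the cause was not tested for these or for the other counts. Intensities, slides and background correction were not analysed here, so filters on dim spots, a slide block and normexp were not run, and what signal over background limits is unknown.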

Other observations

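The genes here were chosen after their values were seen, and no test beyond limma's was run on them. NQO1 and SRXN1, known as targets of the oxidative stress factor NRF2, were at −0.96 ± 0.49 and −0.97 ± 0.21 under siFBP2 and at −1.44 ± 0.31 and −1.27 ± 0.39 in siFBP2 minus siFBP3, past the test adjusted over the list alone. The oxidative stress list itself did not pass in either comparison (shift 0.09, adjusted p = 0.520, and shift −0.12, adjusted p = 0.464). The histone variant gene H2AX was at −1.47 ± 0.69 and the disintegrin protease genes ADAM12 and ADAM10 were at −1.26 ± 0.12 and −0.97 ± 0.53 under siFBP2. CTSK and MMP11 were at 1.18 ± 0.77 and 1.09 ± 0.48 under siFBP1, and KRT1, a keratin of differentiated epidermis, was at −1.61 ± 0.13 under siFBP3. Each of these was past the test adjusted over its list alone and short of it over all features.

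PTGS2 and CXCL8, inflammatory genes with AU-rich mRNAs, were higher under siFBP2 than under siFBP3, at 1.92 ± 0.05 and 1.42 ± 0.02 (adjusted p = 0.024 and 0.022 when adjusted over the list alone of AU-rich mRNAs). They were at 1.07 ± 0.79 and 0.62 ± 0.16 under siFBP2 and at −0.85 ± 0.74 and −0.80 ± 0.15 under siFBP3, so both sides add to the difference. In siFBP1 minus siFBP2, PTGS2 was at −1.95 ± 0.07, with adjusted p = 0.044 over the AU-rich list alone but 0.096 over the list alone of 18 inflammatory genes. The list of 6 AU-rich mRNAs as a whole did not pass between siFBP2 and siFBP3 (shift 0.64, adjusted p = 0.065) or under siFBP2 (shift 0.10, adjusted p = 0.821).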
